A study of Mus musculus with 6 samples.

How the data were processed

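Total RNA was sequenced on a BGISEQ-500 instrument, per the labels' protocols, from 6 libraries of calvarial cells of Eed-floxed mice, 3 infected with an adenovirus for YFP and 3 with an adenovirus for Cre. Groups and replicate numbers were taken from the sample titles, and the table's columns were assigned to samples through the numbers in the sample descriptions. The authors deposited 1 table of FPKM, reads per kilobase of transcript normalised for sequencing depth, with 18216 genes and 1 column per library, per the file headers. Bowtie 02.2.5 and the genome build mm8 are named per the submitters' processing notes. The quantification tool, its filters, the handling of overlapping genes and strand, and the read length are not given in the sources used here. The table holds no coordinates, and the reference used here is of a later build than the one named, so no coordinates are printed.

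The design fixed before the data were examined assumed counts and gave another test for a table with FPKM alone, and that test was used. FPKM were put on the log2(FPKM + 1) scale, and genes with at least 1 FPKM in at least 3 libraries were tested, 12026 in all, leaving 6190 out. limma 3.58.1 in R 4.3.3 fitted the groups with no covariate, with an intensity trend and robust empirical Bayes moderation and 4 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05, and are two-sided. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and means and SDs are of FPKM over the 3 libraries of a group. A value of 0 in such a table can be a failed estimate, so no fold is given against a group listed at 0.

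Depth was recovered from the deposited FPKM. Values between 0.1 and 0.5 FPKM of genes with transcripts under 1500 nt fell close to whole numbers of reads, with a mean distance to a whole number of 0.104 to 0.119 against 0.25 with no steps, for depths of 14850000 to 15050000 reads and an assumed read length of 50 nt. The depth so obtained was even across libraries. The numbers of reads given beside a gene follow from it and from the transcript length, and cover counting error only. Reads were not recovered for all genes, since the lengths the authors used are not in the table, and no count-based test was run.

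Gene symbols were taken from the table. Spreadsheet software had turned 27 of them into dates, and all 27 were restored through their gene identifiers. Before the data were examined, 46 gene lists were fixed, with 1033 entries, of which 942 matched a gene of the table and 653 were tested. They cover Polycomb complexes and their targets, cell cycle, signalling, stress and metabolic pathways, and markers of bone, cartilage and other cell types the cultures could hold. For each of the 39 lists with at least 3 tested members, the number of genes past the test was counted over all genes tested and adjusted over the list alone. limma's camera, with a preset correlation of 0.01, compared the list with the other genes, adjusted over the 39 lists. No camera call held with the correlation between genes estimated per list, where the lowest adjusted p was 0.0545 and 11 of the 39 lists had an unadjusted p under 0.05. fry, which tests whether a list's genes move on balance one way without comparing them with other genes, called 20 lists.

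The genes named follow a rule fixed before the data were examined: the PRC2 list, the 12 largest changes in each direction among genes past the test whose groups do not overlap and whose higher group reaches 1 FPKM, the 5 most abundant genes past the test in each direction, and up to 4 genes with the smallest adjusted p of each list. Among the genes past the test, 7 known only by a model or clone name were left out of the naming. Isg15 and the genes named among the other observations were chosen after their values were seen.

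The gene test was run on simulated values for the same 12026 genes of this comparison. It recovered 59.7% of 67 genes planted with a 1.5-fold change, 82.1% of 67 with a 2-fold change and 97% of 66 with a 3-fold change, and 9 of its 168 calls (5.36%) were false. A shift of -0.3 planted in the chondrocyte list was found and no other list was called. The simulated noise was drawn independently for each gene. It therefore cannot show how often lists whose genes vary together, or single genes that share a trend of a library, are called falsely. Other settings chosen beforehand were a pseudocount of 0.1, no filter and a stricter filter of a mean of 5 FPKM, the replicate number as a block, each library left out, thresholds of 0.01 and 0.1, an estimated correlation and fry. Added after seeing the data were scaling by the median of ratios, by the upper quartile and to an equal sum of FPKM, removal of a length and GC trend per library (loess, span 0.3), leaving out features under 200 nt, a fit with no intensity trend, and leaving members of the immediate early list out of the other lists. Transcript length and GC content came from GENCODE transcripts for 98.7% of the tested genes. Figures were drawn with matplotlib in Python.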

Results

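RNA was measured in 6 libraries of cells grown out of the calvaria, the flat bones of the skull vault, of mice carrying a floxed Eed gene on both alleles. Eed encodes a core subunit of Polycomb repressive complex PRC2, which methylates a lysine of histone H3 and keeps developmental genes silent. The mice were at postnatal day 10, and the cells left collagenase-treated bone chips and grew to 80% confluency. In the YFP group (n = 3) they were infected for 3 days with an adenovirus carrying a yellow fluorescent protein. In the Cre group (n = 3) the adenovirus carried Cre recombinase, which cuts out DNA between loxP sites, and the labels give no time of infection for it. The series title calls the cells mesenchymal stem cells. The labels do not say whether the replicates came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical.

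The deposited values are FPKM, reads per kilobase of transcript normalised for sequencing depth. Between 11906 and 12045 genes per library reached 1 FPKM, and the steps between low values put the depth at 14850000 to 15050000 reads per library for an assumed read length of 50 nt. At the median of 14900000 reads, 1 FPKM over 2000 nt stands for about 29.8 reads. All 15 pairs of libraries were close, with Pearson's r of log2(FPKM + 1) across genes between 0.987 and 0.994. Pairs within a group exceeded pairs between groups by 0.00163 on average, but the ranges overlapped. YFP replicate 3 and Cre replicate 1 reached 0.992, against 0.9895 for Cre replicates 1 and 3. The leading principal component held 30.8% of the variance, and all YFP libraries lay on one side of it and all Cre libraries on the other, with YFP replicate 1 farthest out. The gap was small: YFP replicate 3, at -1.01, lay nearer to Cre replicate 3, at 5.20, than to YFP replicate 1, at -17.85. The libraries at its ends, YFP replicate 1 and Cre replicate 1, also had the strongest trends of their deviations with transcript length (Spearman's rho -0.354 and 0.398). The component and this trend were not separated.

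The comparison of Cre with YFP asks what changes in these cells once Eed is recombined. Eed itself fell from 16.7 ± 0.892 FPKM in YFP to 5.29 ± 0.223 in Cre (SD, n = 3 each), a ratio of 0.316. Its values were 17.75, 16.32 and 16.11 FPKM in the YFP libraries and 5.2, 5.12 and 5.54 in the Cre libraries, so the floxed gene matched the label in all 6. On the log2(FPKM + 1) scale the change was -1.49 (SE 0.08, limma adjusted p = 6.46e-06), resting on about 503 reads per YFP library and 159 per Cre library. The value covers the whole gene and does not separate reads of the deleted part from reads outside it.

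The other 10 measured members of the PRC2 list did not pass the test. Ezh2, the methyltransferase of the complex, stood at 10.8 ± 0.480 FPKM in YFP and 10.8 ± 1.09 in Cre, and Suz12 at 8.45 ± 0.882 and 8.79 ± 0.816 (SD, n = 3). Aebp2 had the smallest adjusted p among them, with 25.3 and 28.5 FPKM (limma adjusted p = 0.436). Ezh1 stood at 5.69 and 5.30 FPKM and Jarid2 at 3.60 and 3.24. Over the list, 0 genes rose and 1 fell, over all genes tested and also adjusted over the list alone, and camera gave an adjusted p = 0.176. None of the 20 tested members of PRC1, the other main Polycomb complex, passed over all genes. Bmi1 came closest at 14.3 and 18.5 FPKM (limma adjusted p = 0.0544), and 2 members passed, upward, adjusted over the list alone.

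**Figure D1:**
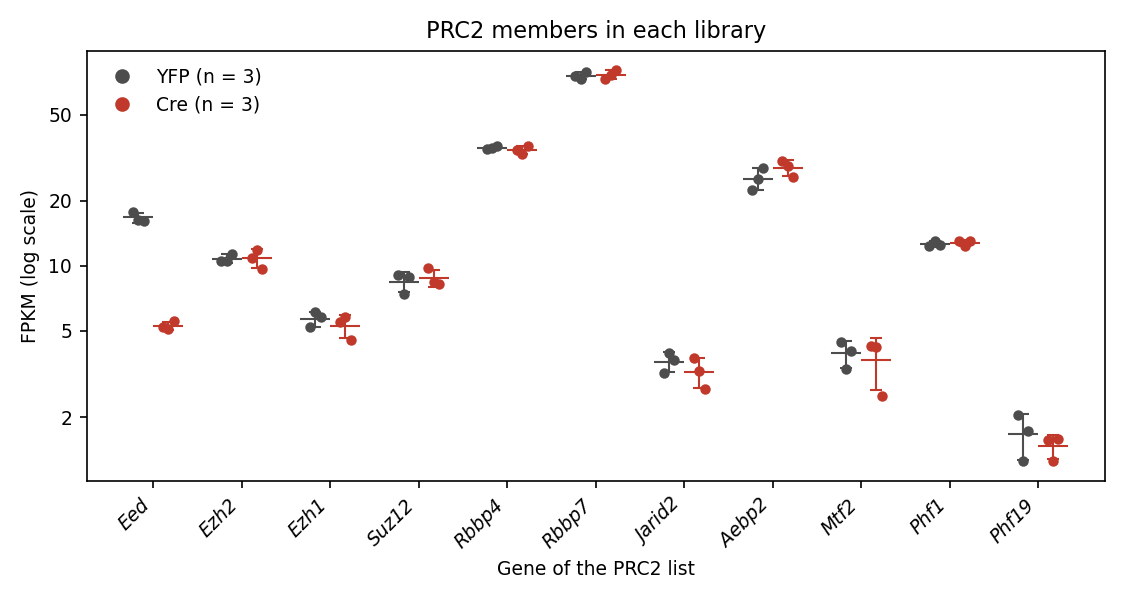
FPKM of each PRC2 list member on a log axis, in the 3 YFP libraries (grey) and the 3 Cre libraries (red), with the mean as a horizontal bar and the SD as the error bar. Eed falls from a mean of 16.7 to 5.29 FPKM, while the groups of the other 10 members overlap.

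Across 12026 tested genes, 58 were higher and 35 lower in Cre at a false discovery rate of 0.05, most of them by a modest factor. Egr1, a transcription factor induced within minutes of growth or stress signals, rose most on the log2(FPKM + 1) scale, from 25.5 ± 3.72 to 58.8 ± 3.57 FPKM (SD, n = 3), with a log2 fold change of 1.18 (SE 0.09, limma adjusted p = 0.000421). Ch25h, the enzyme that makes 25-hydroxycholesterol, rose from 4.63 to 9.03 FPKM, elastin (Eln) from 10.6 to 17.5, and Alpl, the bone alkaline phosphatase, from 11.2 to 17.6. The cytokine Il11 rose from 2.81 to 4.81 FPKM, the LIF receptor gene Lifr from 4.30 to 7.04, Efna3 from 1.12 to 2.36, Lrrc15 from 6.97 to 10.9 and Celf5 from 2.01 to 3.45. Among genes that fell, F13a1, the A chain of coagulation factor XIII, went from 22.5 ± 1.55 to 13.9 ± 0.332 FPKM (limma adjusted p = 0.00491). Matn4, a matrix protein gene, fell from 3.92 to 2.14 FPKM, G0s2, an inhibitor of triglyceride breakdown, from 3.88 to 2.13, the mitochondrial ribosome gene Mrps12 from 20.7 to 12.7, and P4htm from 2.60 to 1.35.

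The most abundant genes that rose were Cyr61 (188 to 253 FPKM), the protease inhibitor Timp3 (110 to 148), the collagen crosslinking enzyme Loxl2 (108 to 144), Ass1 (63.1 to 93.4) and the collagenase Mmp13 (59.6 to 87.2). The most abundant that fell were Aldoa (797 to 596 FPKM), Gas1 (116 to 88.0), Ap2s1 (115 to 89.1), Idh2 (69.9 to 51.5) and Sf3b5 (68.3 to 52.6). A pair of small nucleolar RNAs also passed. Snord22 rose from 8.08 to 16.3 FPKM, about 9.27 and 18.7 reads, and Snord14e was at 2.51, 3.74 and 3.7 FPKM in the YFP libraries and listed at 0 in each Cre library. Snord14e spans 90 nt and rested on about 2.03 reads per YFP library, and both lie inside host genes, with the handling of overlapping reads not given in the sources used here.

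The median ratio of means was 1.46 among the genes that rose and 0.680 among those that fell, and 3 genes past the test differed by at least 1 on the log2(FPKM + 1) scale: Egr1, Eed and Snord14e. The last rests on a group listed at 0, which can be a failed estimate, and with features under 200 nt left out the count was 2. The FPKM ranges of the groups were separate for all 93 genes, which passing the test with 3 libraries per group all but requires. They were separate for 20.7% of the genes tested, against 10% by chance for any single gene. Genes share trends across libraries, so this share was not tested against chance. The genes that fell had a median transcript length of 1397 nt and those that rose 3000 nt. With the length and GC trend of each library removed, 74 rose and 26 fell, and with each library scaled to an equal sum of FPKM, 99 rose and 36 fell. The count depended on the libraries: 18 genes passed without YFP replicate 1, 6 without YFP replicate 2, 25 without YFP replicate 3, 61 without Cre replicate 1, 9 without Cre replicate 2 and 33 without Cre replicate 3. It was 8 with no filter on low values and 27 with no intensity trend. Eed, Egr1 and F13a1 passed in each of the 17 settings that refitted all genes, and 48 of the 93 genes passed in most of them. Several named genes passed in few: G0s2 and Acta1 in 5, Acp5 and Tnfrsf11b in 6, and Mcm5 and Aldoa in 7. All 93 genes kept their direction in these settings, wherever they were tested. Since their groups do not overlap, only the scalings and the removal of the length and GC trend could have turned a direction.

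**Figure D2:**
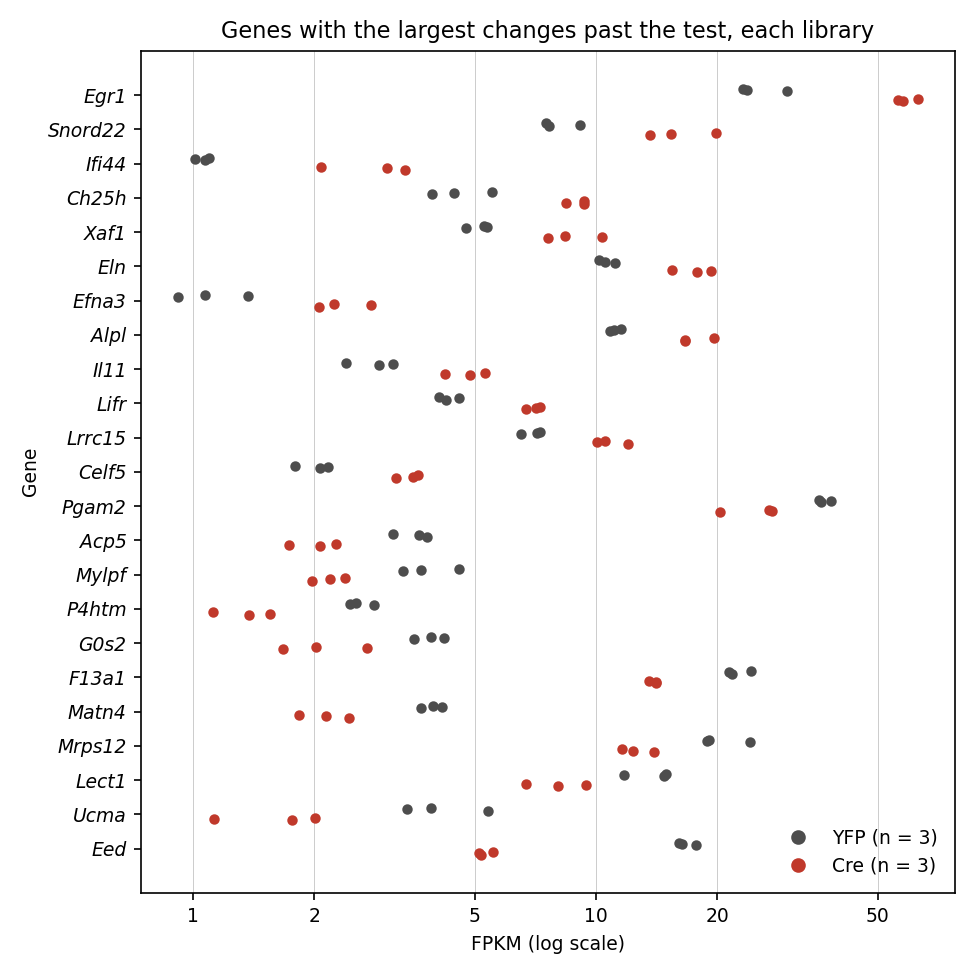
FPKM in each library, on a log axis, of the named genes with the largest log2 fold changes past the test, leaving out Snord14e, which is listed at 0 in the Cre libraries. Points are single libraries, YFP in grey and Cre in red, and the groups do not overlap for any gene shown, as for Egr1, with means of 25.5 and 58.8 FPKM.

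Genes of the cell cycle were lower as a group in Cre, in which immediate early genes, described below, were higher (median log2 fold change 0.26). The proliferation list, 24 mitotic and cell cycle genes, had a median log2 fold change of -0.22 with 23 of 24 members lower (camera adjusted p = 1.57e-10, and adjusted p = 0.0545 with an estimated correlation). None of its members passed over all genes tested, 15 were lower at an unadjusted p under 0.05, and 13 were lower adjusted over the list alone. Examples are Ccna2 at 31.3 and 25.5 FPKM, Cdk1 at 19.2 and 15.1, and Birc5 at 48.1 and 38.0. The 26 DNA replication genes had a median of -0.18 (camera adjusted p = 3.01e-09, and adjusted p = 0.0545 with an estimated correlation). Mcm5, part of the replicative helicase, fell from 16.7 ± 1.04 to 12.4 ± 0.449 FPKM (SD, n = 3, limma adjusted p = 0.0351), and 12 members were lower adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, stood at 31.1 and 26.3 FPKM.

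Targets of the tumour suppressor p53 were higher as a group, as immediate early genes were, with 21 of 25 above 0 and a median log2 fold change of 0.22 (camera adjusted p = 9.08e-08, and adjusted p = 0.0545 with an estimated correlation). No member passed over all genes tested, while 17 were higher and 3 lower at an unadjusted p under 0.05, and 15 higher and 1 lower adjusted over the list alone. Mdm2, which feeds back on p53, stood at 43.7 and 53.8 FPKM, Cdkn1a, which encodes the cell cycle inhibitor p21, at 274 and 349, Phlda3 at 81.2 and 97.9, and Perp at 5.11 and 7.10. Of the 7 INK4 and KIP cell cycle inhibitors, 0 passed over all genes tested and 1, Cdkn1a, adjusted over the list alone (camera adjusted p = 0.631). Cdkn2a, a classical Polycomb target in cultured cells, had 14.4 ± 0.740 FPKM in YFP and 16.5 ± 1.13 in Cre (SD, n = 3, limma adjusted p = 0.307).

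The chondrocyte list was lower and the osteoblast list higher in Cre by camera, though most members of either did not pass over all genes tested, and immediate early genes were higher in the same libraries (median log2 fold change 0.26). In the chondrocyte list 3 of 16 tested genes fell: Ucma from 4.23 to 1.63 FPKM, Lect1 (chondromodulin) from 13.8 to 8.06, and Col9a1 from 11.9 to 7.96. Adjusted over the list alone 8 fell, and the median log2 fold change was -0.23 (camera adjusted p = 6.12e-07, and adjusted p = 0.0545 with an estimated correlation). Matn3 stood at 4.86 and 3.13 FPKM. In the osteoblast list, Mmp13 and Alpl rose, 4 genes rose and 1 fell adjusted over the list alone, and the median was 0.20 (camera adjusted p = 0.00117, and adjusted p = 0.0846 with an estimated correlation). Runx2, the master regulator of the lineage, stood at 10.4 and 12.8 FPKM (limma adjusted p = 0.111), and Col11a2 at 6.36 and 4.63.

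Camera also called the tendon, skeletal progenitor and skeletal muscle lists. In the tendon list Egr1 alone of 12 genes rose over all genes tested, 5 rose and 1 fell adjusted over the list alone, and the median was 0.16 (camera adjusted p = 0.00157, and adjusted p = 0.0846 with an estimated correlation). Egr1 and Egr2 are also in the list of immediate early genes, which were higher in Cre (median 0.26), and without these 2 the tendon call ended (median 0.11, camera adjusted p = 0.0889, and adjusted p = 0.26 with an estimated correlation). Thbs4 stood at 6.02 and 8.35 FPKM and Fmod at 316 and 388. In the skeletal progenitor list Grem1 rose from 36.2 to 47.5 FPKM and 18 of 19 genes did not pass, with 2 up adjusted over the list alone and a median of 0.07 (camera adjusted p = 0.0185, and adjusted p = 0.198 with an estimated correlation). That call ended without YFP replicate 1 (median 0.045, camera adjusted p = 0.0576), without Cre replicate 1 (median 0.068, camera adjusted p = 0.0535) and at a mean of at least 5 FPKM (median 0.063, camera adjusted p = 0.0726). Mylpf, a myosin light chain, and Acta1, skeletal actin, fell from 3.87 to 2.18 and from 8.30 to 5.91 FPKM. These are 2 of the 3 tested skeletal muscle genes, over all genes and also adjusted over the list alone (median -0.43, camera adjusted p = 0.0185, and adjusted p = 0.264 with an estimated correlation). The third, Tnnt3, stood at 1.21 and 1.66 FPKM. The muscle call ended without Cre replicate 1 (median -0.39, camera adjusted p = 0.196) and with the length and GC trend removed (median -0.35, camera adjusted p = 0.0636).

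Several lists of signalling genes were higher by camera, with few members past the test over all genes, in the libraries in which immediate early genes were higher (median log2 fold change 0.26). Among 10 Wnt inhibitors, Sfrp2 rose from 43.0 to 61.9 FPKM and Sfrp1 from 20.4 to 28.1, both also adjusted over the list alone (median 0.21, camera adjusted p = 0.000312, and adjusted p = 0.0846 with an estimated correlation). Among 12 beta-catenin targets, Nkd2, itself an antagonist of Wnt signalling, rose from 12.4 to 18.2 FPKM, with 2 up adjusted over the list alone (median 0.17, camera adjusted p = 5.27e-05, and adjusted p = 0.0846 with an estimated correlation). Axin2 stood at 2.09 and 2.74 FPKM. The 17 Wnt ligands and receptors held no gene past the test over all genes, with 4 up and 2 down adjusted over the list alone (camera adjusted p = 0.0935). Rspo2 stood at 12.8 and 16.4 FPKM and Fzd9 at 3.96 and 2.51.

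Of 22 TGF-beta ligands, receptors and targets, the activin subunits Inhba (31.2 to 43.0 FPKM) and Inhbb (11.5 to 15.8) and the ligand Tgfb2 (21.4 to 27.7) rose. Adjusted over the list alone, 3 rose and 1 fell, and the median was 0.13 (camera adjusted p = 0.000139, and adjusted p = 0.164 with an estimated correlation). Tgfbi stood at 159 and 130 FPKM. Of 26 BMP ligands, antagonists and targets, the antagonists Grem1 and Fst rose, Fst from 16.8 to 22.5 FPKM, and 6 rose adjusted over the list alone (median 0.05, camera adjusted p = 0.00173, and adjusted p = 0.198 with an estimated correlation). Bmp4 stood at 18.4 and 23.7 FPKM. The 22 FGF and IGF pathway genes were higher as a group with none past the test over all genes, 7 up at an unadjusted p under 0.05 and 3 up adjusted over the list alone (median 0.12, camera adjusted p = 0.00173, and adjusted p = 0.0846 with an estimated correlation). Igfbp2 stood at 199 and 249 FPKM and Fgf7 at 44.3 and 54.3. Of 8 Hedgehog pathway genes, Gas1, a co-receptor, fell, also adjusted over the list alone (camera adjusted p = 0.181).

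Immediate early genes, which also respond to handling of cells before lysis, were higher in Cre. Egr1, Ier2 (15.2 to 21.4 FPKM), Ier3 (30.3 to 42.3) and Dusp1 (17.5 to 26.0) rose among 17 tested, and 13 rose and 1 fell adjusted over the list alone. The median was 0.26 (camera adjusted p = 6.48e-09, and adjusted p = 0.0846 with an estimated correlation). Of 22 genes of the type I interferon response, Ifi44 rose from 1.06 to 2.83 FPKM and Xaf1 from 5.13 to 8.79, with 3 up adjusted over the list alone (median 0.32, camera adjusted p = 7.33e-07, and adjusted p = 0.342 with an estimated correlation). Its members varied together within groups, with an estimated correlation of 0.489, and fry gave an adjusted p = 0.147. Isg15, for example, was at 2.9, 8.74 and 6.36 FPKM in the YFP libraries and 15.37, 10.86 and 11.04 in the Cre libraries. Of 16 inflammatory cytokines and chemokines, Ccl7 rose from 14.3 to 20.4 FPKM, with 5 up adjusted over the list alone (median 0.26, camera adjusted p = 4.36e-05, and adjusted p = 0.0897 with an estimated correlation). Il6 stood at 2.0 and 3.38 FPKM.

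Genes of glycolysis were lower as a group in the libraries with higher immediate early genes (median log2 fold change 0.26). Aldoa fell, 5 of 21 fell adjusted over the list alone, and the median was -0.17 (camera adjusted p = 1.01e-05, and adjusted p = 0.169 with an estimated correlation). Ldha stood at 597 and 479 FPKM and Tpi1 at 270 and 221. Pgam2, the muscle form of phosphoglycerate mutase and not in the list, fell from 36.7 to 24.9 FPKM. Matrix genes were mixed. Of 21 matrix remodelling enzymes Mmp13, Timp3 and Loxl2 rose, with 4 up and 3 down adjusted over the list alone (camera adjusted p = 0.0914). Of 19 collagens Col8a1 rose from 41.7 to 59.8 FPKM, with 2 up adjusted over the list alone (camera adjusted p = 0.163).

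**Figure D3:**
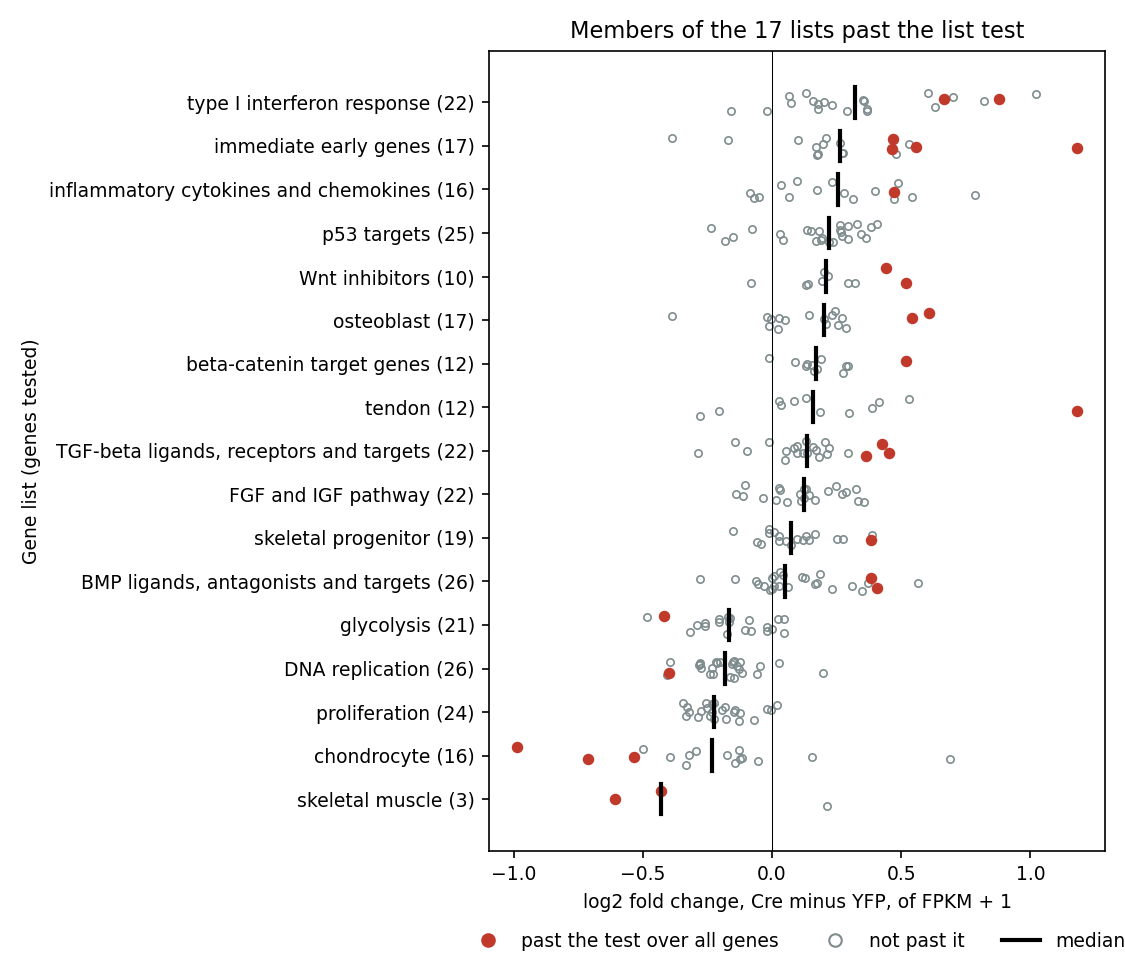
Log2 fold change (Cre minus YFP, FPKM + 1) of each tested member of the 17 lists past camera with a preset correlation. Filled red points passed the test over all genes, open points did not, and black bars are list medians, from 0.32 for the type I interferon response to -0.43 for the 3 skeletal muscle genes.

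Classical developmental targets of Polycomb that were expressed highly enough to test did not pass it. Of 33 Hox genes with a value, 7 were expressed highly enough to test, and none passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05 in limma (camera adjusted p = 0.841). Hoxb3 stood at 2.2 and 2.52 FPKM and Hoxd8 at 3.81 and 3.38. Of 117 other developmental transcription factor genes with a value, 43 were expressed highly enough to test. None of the 43 passed over all genes or adjusted over the list alone, and 3 were higher at an unadjusted p under 0.05 in limma (camera adjusted p = 0.943). Dlx5 stood at 21.6 and 25.6 FPKM and Tbx18 at 2.68 and 3.30. The genes of both lists left out did not reach 1 FPKM in at least 3 libraries, so targets that stayed below it are not covered. None of 20 imprinted genes passed over all genes, 5 were higher at an unadjusted p under 0.05, and 2 were higher adjusted over the list alone (camera adjusted p = 0.158), with Meg3 at 134 and 162 FPKM. By unadjusted p under 0.05, 1727 of all tested genes moved, 876 up and 851 down.

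The remaining lists gave no call by camera. Of 6 osteoclast genes Acp5, which encodes tartrate-resistant acid phosphatase, fell from 3.52 to 2.02 FPKM, over all genes and adjusted over the list alone (camera adjusted p = 0.943). No member passed over all genes in the lists of osteocyte (camera adjusted p = 0.659), adipocyte (0.943), myofibroblast (0.252), macrophage (0.405), neuron (0.158) and glia (0.209) genes. Adjusted over the list alone, 1 adipocyte gene, Lpl, was lower and 2 neuron genes, Gap43 and Stmn2, were higher. The lists of histone H3K27 demethylases and MLL methyltransferases (camera adjusted p = 0.446), antigen presentation (0.943), cholesterol synthesis (0.544), unfolded protein response (0.895) and ribosomal protein genes (0.0589) held no gene past either count. The median and the test differed in sign for the adipocyte, osteoclast, unfolded protein response and other developmental transcription factor lists, whose medians were 0.01, 0.02, 0.02 and 0.02 with means of -0.02, -0.04, -0.01 and -0.01. Germline, erythroid and lymphoid genes had no member at the tested level, neutrophil and keratinocyte genes 1 each and endothelial genes 2, and mitochondrially encoded genes had no value to use.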

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

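The scalings, the removal of the length and GC trend, the features under 200 nt left out, the fit with no intensity trend and the immediate early members left out of other lists were chosen after seeing the data. Eed fell in every setting, and the count of lists, 17 as reported, stayed between 15 and 19 with camera and was 20 with fry, but 0 with an estimated correlation. An estimated correlation also leaves camera only 4 degrees of freedom, which limits how small its p can be. The count of genes, 93 as reported, was 8 with no filter on low values (5 of them shared), 13 at a threshold of 0.01, 305 at 0.1 and 27 with no intensity trend, and 6 to 61 with 1 library left out. The count at least 2-fold, 3 as reported with Snord14e, listed at 0 in Cre, was 2 with features under 200 nt left out, 9 with a pseudocount of 0.1, where differences of low genes weigh more, and 3 to 8 with 1 library left out (6 without Cre replicate 1, 5 without Cre replicate 2 and 8 without Cre replicate 3). A fit with fewer samples has less power by construction, and the cause of the lower counts without the filter or the intensity trend was not tested. Deviations of libraries with the same number correlated at -0.152, -0.0584 and -0.144, and no library correlated best with its own number. These values gave no sign of pairing but, with 3 libraries per group, cannot exclude it. With the replicate block 54 genes passed, 42 of them shared, and 5 changed at least 2-fold. Among lists, skeletal progenitor genes lost their call at a mean of at least 5 FPKM (median 0.063 against 0.073 as reported, camera adjusted p = 0.0726). Skeletal muscle genes lost it with the length and GC trend removed (median -0.35 against -0.43, camera adjusted p = 0.0636). Tendon genes lost it without the immediate early members Egr1 and Egr2 (median 0.11 against 0.16, camera adjusted p = 0.0889). Ribosomal protein genes passed as lower without YFP replicate 3, without Cre replicate 2, without Cre replicate 3 and with an equal sum of FPKM. Calls were also gained upward by PRC1 genes at a mean of at least 5 FPKM (adjusted p = 0.0329) and without YFP replicate 1 (adjusted p = 0.0495), by Wnt ligands and receptors at a mean of at least 5 FPKM (adjusted p = 0.00265), and by collagens without Cre replicate 3 (adjusted p = 0.0322). With fry the PRC2, Wnt ligand, neuron and matrix enzyme lists passed and the interferon list did not. The PRC2 list holds the recombined gene Eed (log2 fold change -1.49), its other 10 members did not pass the gene test, and fry was not run without Eed. The tests and normalizations planned for counts were not run, since the values are FPKM. At about 14900000 reads per library, 1 FPKM over 2000 nt rests on about 29.8 reads and shorter features on fewer.

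Directions turned only for genes and list medians that did not pass the test, and the cause was not tested. Genes past the test have groups that do not overlap, so only the scalings and the trend removal could have turned them. Ezh2 went to 0.0025 with upper-quartile scaling and 0.026 with an equal sum, Suz12 to -0.0053 and Rbbp7 to -0.0089 with the length and GC trend removed. With 1 library left out, Ezh2 ranged from -0.064 to 0.069, Suz12 from -0.027 to 0.10, Rbbp4 from -0.063 to 0.00035, Rbbp7 from -0.020 to 0.048, Mtf2 from -0.20 to 0.089, Hoxa5 from -0.028 to 0.31, Tnnt3 from -0.015 to 0.51, Clcn7 from -0.0098 to 0.083 and Mbp from -0.0057 to 0.17. Medians turned to 0.028 (Hox) and -0.020 (adipocyte) with no filter, to 0.0064 (PRC2) and -0.035 (adipocyte) at a mean of at least 5 FPKM, to -0.00012 (PRC1) with median-of-ratios scaling, to 0.0095 (cholesterol synthesis) with an equal sum, and to -0.014 (collagens) and 0.00997 (ribosomal proteins) with the trend removed. With 1 library left out, medians ranged from -0.029 to 0.096 for PRC1, -0.017 to 0.050 for other developmental transcription factors, -0.0086 to 0.037 for adipocyte, -0.072 to 0.088 for antigen presentation, -0.030 to 0.068 for collagens, -0.066 to 0.013 for cholesterol synthesis, -0.0092 to 0.027 for the unfolded protein response and -0.11 to 0.025 for ribosomal proteins.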

Other observations

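Several genes outside the fixed lists rose with Cre, named here after their values were seen. Cyp26b1, which degrades retinoic acid, went from 4.15 ± 0.0964 to 6.51 ± 0.751 FPKM (SD, n = 3, limma adjusted p = 0.0302), and Ahr, the aryl hydrocarbon receptor gene, from 21.8 ± 0.746 to 28.8 ± 1.64 (limma adjusted p = 0.032). Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor that restrains osteoclast formation, went from 52.9 to 69.8 FPKM (limma adjusted p = 0.0498), and Pappa, a protease that frees IGF from its binding proteins, from 21.8 to 31.7 (limma adjusted p = 0.0198). Ptprn rose from 9.73 to 14.8 FPKM, Fhl1 from 18.6 to 27.6 and Npr3, a clearance receptor for natriuretic peptides, from 11.6 to 16.6. Slpi, a secreted protease inhibitor, fell from 18.9 to 12.9 FPKM and Ndufa4l2, a gene induced by hypoxia, from 19.3 to 14.02.

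The table's own process annotation, tested with camera after the lists had been seen, gave 508 terms of 15 to 500 genes, of which 39 were higher and 16 lower in Cre, and 0 passed with an estimated correlation. Higher were the BMP signaling pathway (35 genes, median log2 fold change 0.16, camera adjusted p = 0.00103), the response to glucocorticoid (29 genes, median 0.16, camera adjusted p = 0.00121), tissue remodeling (33 genes, median 0.17, camera adjusted p = 0.00165) and ossification (63 genes, median 0.08, camera adjusted p = 0.00414), each with an adjusted p = 0.54 with an estimated correlation. The smallest p-values of all terms were for lower DNA-dependent DNA replication (42 genes, median -0.14) and S phase (97 genes, median -0.095). Each had a camera adjusted p = 9.11e-05, and 0.54 with an estimated correlation. Also lower were telomere maintenance (25 genes, median -0.15, camera adjusted p = 0.00128), nucleosome organization (52 genes, median -0.07, camera adjusted p = 0.0161) and proteasomal protein breakdown (113 genes, median -0.05, camera adjusted p = 0.0115), with an adjusted p = 0.54, 0.564 and 0.54 with an estimated correlation. Unlike the p53 target list, cell cycle arrest was lower (112 genes, median -0.06, camera adjusted p = 0.00448, and adjusted p = 0.54 with an estimated correlation). The term for p53 signalling after DNA damage did not pass (58 genes, median -0.04, camera adjusted p = 0.167). With the length and GC trend removed, 48 of the terms passed in the same direction. With an estimated correlation, which leaves camera only 4 degrees of freedom, the lowest adjusted p was 0.54, and 35 terms had an unadjusted p under 0.05. Immediate early genes were higher in the same Cre libraries (median log2 fold change 0.26).

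Of the tests that follow, the removal of the length and GC trend and the tests on the lengths of the called genes, on the shared shift of the cartilage genes, on Cre without floxed Eed and on other splits of the libraries were chosen after the results were seen. The genes that fell were shorter than those that rose, with medians of 1397 and 3000 nt (permutation p = 3e-05, two-sided), and richer in GC, with 55.9% and 50.7%. The permutation shuffled genes as if they were independent, so its p does not measure the spread between libraries. Across 11870 tested genes, which are not independent, the log2 fold change had a Spearman's rho of 0.277 with length and -0.247 with GC, and libraries of one group already differed in it, with a rho of their deviations with length from -0.354 to 0.0968 among the YFP libraries. With the trend removed from each library, 70 of the 93 genes still passed. Whether the trend is technical was not decided, since its removal evens the lengths of called genes whatever its cause. The falls themselves kept 82.3% of their median size (bootstrap interval 79.7 to 96.3), so the trend is not their whole cause, and they meet the bound of 80% set beforehand. The bootstrap resampled genes and not libraries, so its interval leaves out the spread between libraries. That bound lies inside the interval, which was added after, so a partial share of the trend stays open.

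Lower cell cycle genes beside higher p53 targets were weighed against technical and biological explanations. With the length and GC trend removed, the medians of the proliferation, DNA replication and p53 lists kept at least 80.5% of their size and all 3 still passed camera, which argues against the trend as the cause. With any 1 library left out they kept at least 90.7%, which argues against a single deviating library. Damage by Cre recombinase itself, which can cut at sites that resemble loxP, and the loss of Eed cannot be told apart: 0 of the Cre libraries lack floxed Eed. Immediate early genes, which respond to handling before lysis, were higher in the same group (median log2 fold change 0.26, camera adjusted p = 6.48e-09, and adjusted p = 0.0846 with an estimated correlation), and a difference in handling or in time since infection, which the labels do not give for Cre, was not tested and stays open.

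The lower chondrocyte list kept 100% of its median with the length and GC trend removed, and the median stayed between -0.24 and -0.21 with 1 library left out, which argues against both as its cause. An equal loss of cartilage cells of every kind would lower genes made by those cells alone by one factor, and on the log2(FPKM + 0.1) scale the 16 genes as a set lay apart from one shared shift (limma's mroast, both directions, adjusted p = 0.00886 over the lists). Ucma lay lower than the shared log2 ratio of -0.29 by a further -1.04 (limma adjusted p = 0.0171 over the list) and Lect1 by -0.48 (limma adjusted p = 0.0396), while Prg4 lay higher by 0.99 and Col10a1 by 0.54, both short of the threshold (limma adjusted p = 0.0632). The set test held without Ucma and Lect1 (limma's mroast, adjusted p = 0.0113) but ended without YFP replicate 3 (adjusted p = 0.0538) and without Cre replicate 2 (adjusted p = 0.0575), 14 of the 39 lists passed it, and whether other cells make these transcripts was not tested. So an equal loss, a loss limited to some cartilage cells and lower expression within them after Cre or loss of Eed all stay open.

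Loss of a Polycomb subunit could switch on silent genes. Of 4849 genes under 0.5 FPKM in all YFP libraries, 25 reached it in all Cre libraries, while 15 went the other way (exact binomial p = 0.154, two-sided). The excess did not pass, and the bound written beforehand, a p of at least 0.05, was too weak to exclude a small effect, so, judged after the result, the test leaves it open. From under 0.1 FPKM in all YFP libraries, 1 gene reached 0.5 FPKM in all Cre libraries. It was Snora62, a small nucleolar RNA, listed at 0 in each YFP library and at 0.73, 0.73 and 2.93 FPKM in the Cre libraries. As for Snord14e, a value of 0 can be a failed estimate.

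The 6 libraries form 10 splits into groups of 3, so no share under 0.1 can be reached. The real split gave 93 genes and 17 lists, each in 1 of the 10 splits, and the highest other split gave 3 genes and 7 lists. Each other split mixes YFP and Cre libraries, so the difference between the groups enters its residual spread and lowers its counts. Those counts are therefore not a clean chance level. For genes changed at least 2-fold, Snord14e included, the real split gave 3, and 2 of the 10 splits gave as many, with 3 as the highest other.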
